A study of Homo sapiens with 16 samples.

How the data were processed

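Total RNA from U-87MG cells was profiled on 16 single-colour arrays, 4 for each of DMSO, I3P, SR1 and I3P+SR1. Per the labels' protocols, RNA was prepared on columns and 100 ng of total RNA was labelled with an Affymetrix whole-transcript kit. The deposited values are log2 expression values, 1 per transcript cluster and array. Per the submitters' processing notes, oligo and RMA were used, a combination that corrects background, quantile normalizes the arrays and summarizes probes, and no version was named. The genome build, the annotation, the filter that left 16510 rows and the length of treatment are not given in the sources used here, so no coordinates are printed. The values ran from 2.13 to 13.8, with near-equal medians on all arrays, as RMA leaves them. Quantile normalization assumes that most genes keep their level, and RMA compresses differences of dim genes, so changes of genes such as CYP1A1 can be understated. No raw intensities or detection calls were used here, so signal over background was not assessed.

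Rows were named through a table of the platform's annotation. Of 16510 rows, 14096 had 1 symbol, 795 had several and were left out, and 1619 were not listed and stayed unnamed. Where a symbol had more than 1 row (52 genes) the row with the highest mean over all arrays was kept, which gave 14040 genes, and no such gene had rows of opposite sign with a call in SR1 against DMSO. Of the symbols, 12952 were current in the reference gene table, 1088 were found there as older symbols and 0 were missing. Symbols are printed as the platform table gives them. Genes without a row with 1 symbol, such as UGT1A6 of the AHR target battery, were not analysed here.

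Groups and replicate numbers were taken from the labels, which call the arrays biological replicates. No pair of arrays was a duplicate, since the smallest root mean square difference over genes was 0.258. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) was fitted to all 16 arrays with a mean per group and no block, so that the groups shared an estimate of the spread, and the 6 comparisons were contrasts of that fit. The interaction was the change from SR1 to I3P+SR1 minus the change from DMSO to I3P. Adjusted p is the two-sided limma p after Benjamini-Hochberg over the 14040 genes, and a gene passed at an adjusted p under 0.05. Counts at an unadjusted p under 0.05 are given beside some results. Unchanged genes would give a share of about 0.05 of the genes tested, and all 6 comparisons lay below that share in this fit. With the replicate number as a block, some lay above it. Log2 changes are differences of group means, SE is the moderated standard error, and intervals cover 95% for a single gene, without adjustment.

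Lists of genes numbered 28 and were fixed, with the tests, the alternatives and the naming rule, before the data were examined. Each was tested by limma's camera with a preset correlation of 0.01 between genes, with Benjamini-Hochberg over the 28 lists within a comparison, then with an estimated correlation and with fry. The calls of the AHR target battery for SR1 against DMSO, for I3P+SR1 against SR1 and for the interaction hold with the estimated correlation and by fry, and no other camera call does. By fry's test of change in either direction, other reported AHR-responsive genes, retinoid genes and hypoxia genes also passed for SR1 against DMSO and for I3P+SR1 against SR1. Adjusted p of a member "over the list alone" uses Benjamini-Hochberg within the list. The genes named in each comparison were the 12 largest rises and the 12 largest falls among passing genes whose arrays in the first group all lay on the same side of the second group's mean. Where fewer than 5 genes passed, the 5 with the smallest p were named as not passing. Every measured member of the AHR target battery, and up to 4 members with the smallest p from each other list, were also eligible. Uncharacterised loci, small RNA genes and pseudogenes were to be skipped in the ranking, and 0 were met. After a first look at the values, the members given from other lists were limited to those of lists that passed and to members passing over their list alone, and to the AHR gene. The test on pairs of SR1 arrays replaced a first version, on genes called from all arrays, after that version had been seen.

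The replicate numbers were checked for pairing through the correlation, over genes, of the deviations of same-numbered arrays from their group means. These correlations were all above 0.1 for SR1 against DMSO (0.30 to 0.52), I3P+SR1 against SR1 (0.37 to 0.65) and I3P+SR1 against DMSO (0.22 to 0.52). Values with the replicate number as a fixed block are therefore printed beside those comparisons where the block changes a call. For I3P against DMSO and for I3P+SR1 against I3P not all were above 0.1. Each replicate number also has its own prefix in the array titles, which the labels do not explain, so blocked values of lists are printed there too, a choice made after they had been seen. The estimated correlation and fry were run only without the block. Replicate differences stay in those tests, so they cannot decide a list call made with the block. The alternatives were the replicate number as a fixed or random block (duplicateCorrelation, statmod 1.5.0), the title series as a block, each title series alone, a second quantile normalization, centring on the median, leaving out the lowest 25% of genes by mean, eBayes with trend and robust settings, a fit on only the groups compared, all rows without reduction to genes, and each array left out in turn. Array weights, array weights with the replicate block, and the replicate block without I3P replicate 1 were added after seeing the data.

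The fits were tested on simulated data with known changes, put into 67 genes by 0.5, 67 genes by 1 and 66 genes by 2 on the log2 scale for each comparison. For I3P against DMSO, 29.9%, 77.6% and 100% of these were recovered, with 7 false calls among 145, over 14040 genes. For the interaction the shares were 1.49%, 49.3% and 95.5%. The simulated genes were independent, without shared differences between replicate numbers, and many were changed, some by 2. More changed genes loosen the Benjamini-Hochberg cutoff. Where few or no genes changed strongly, as may hold for I3P against DMSO, smaller shares would be recovered. A list changed on purpose in SR1 against DMSO was recovered and 0 of 27 unchanged lists were called. For comparisons that share arrays, 100 sets of unchanged groups were simulated with each gene's residual spread, from the fit without a block and, added after seeing the data, from the fit with the replicate block. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15.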

Results

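Gene expression was measured on 16 arrays from U-87MG, an established human glioblastoma cell line. The cells received the carrier DMSO at 0.1%, indole-3-pyruvate (I3P) at 25 µM, the aryl hydrocarbon receptor (AHR) antagonist SR1 at 1 µM, or I3P and SR1 together. Each of the 4 groups held 4 arrays, described in the labels as biological replicates 1 to 4. I3P is a keto acid derived from tryptophan, and AHR is a ligand-activated transcription factor that controls genes of xenobiotic metabolism. The series asks whether I3P activates transcription through AHR, and the antagonist arms test how far any change depends on the receptor. Values were log2 expression from robust multi-array averaging, and array medians lay between 8.26 and 8.30. Groups were taken as labelled, and the values do not exclude an exchange of the SR1 and I3P+SR1 labels in all replicates. Such an exchange would turn the sign of I3P+SR1 against SR1 and change the values of every other comparison involving SR1. The I3P array of replicate 1 stood apart from the rest, with correlations over genes of 0.877 to 0.910 with the other arrays, against 0.921 to 0.979 among the other 15. The array titles fall into series SLI, with replicates 1 and 2, and series SMI, with replicates 3 and 4, each replicate number has its own title prefix, and each prefix held every group.

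SR1 alone lowered AHR target genes in cells that received no I3P, the comparison that shows what the antagonist does by itself. CYP1B1, a cytochrome P450 and a standard AHR target, was at 10.85 ± 0.10 (SD, n = 4) in DMSO and 8.28 ± 0.11 (SD, n = 4) in SR1, and so fell by 2.57 (SE 0.15) on the log2 scale, a 5.94-fold change with adjusted p = 8.5e-08. AHRR, the AHR repressor induced by the receptor itself, fell by 1.44 (SE 0.18, adjusted p = 0.0019), and TIPARP, an ADP-ribosyltransferase that acts in negative feedback on AHR, fell by 1.34 (SE 0.22, adjusted p = 0.017). The transporter gene SLC16A6 fell by 2.66 (SE 0.42, adjusted p = 0.012), from 9.42 ± 0.93 to 6.76 ± 0.79 (SD, n = 4), where the SR1 mean lay at percentile 2.17 of all genes. In all, 23 of 14040 genes passed for SR1 against DMSO, 22 lower and 1 higher, and for each of the 23 all 4 SR1 arrays lay on one side of the DMSO mean.

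STC2, which encodes a secreted glycoprotein, fell by 1.37 (SE 0.19, adjusted p = 0.0051). EREG, which encodes the EGF receptor ligand epiregulin, fell by 0.95 (SE 0.13, adjusted p = 0.0026). The transcription factor gene ZIC2 fell by 1.33 (SE 0.16, adjusted p = 0.0019) and PLEKHG4B fell by 1.47 (SE 0.19, adjusted p = 0.0026). ZNF295-AS1, RIPK4, ALDH1A3, TMEM119 and ADAMTS18 passed with log2 changes of -1.17, -1.10, -1.06, -1.01 and -0.96. The SR1 means of PLEKHG4B, TMEM119, RIPK4, ADAMTS18 and ZNF295-AS1 lay at percentiles 4.62, 3.03, 1.08, 0.641 and 0.0783 of all genes. BDKRB1, which encodes the bradykinin B1 receptor, was the gene that rose, by 0.84 (SE 0.15, adjusted p = 0.033). BDKRB1 and TMEM119 did not pass without any of the DMSO or SR1 arrays, with adjusted p of 0.067 to 0.18 and 0.053 to 0.16, nor BDKRB1 without I3P+SR1 replicate 2 (0.051) or TMEM119 without I3P+SR1 replicate 1 (0.051) or I3P replicate 2 (0.053). ALDH1A3 did not pass without DMSO replicate 1 (0.14), DMSO replicate 2 (0.14), SR1 replicate 2 (0.066), SR1 replicate 3 (0.14) or SR1 replicate 4 (0.12), and ADAMTS18 did not without DMSO replicate 2 (0.055).

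Of the 11 measured members of the AHR target battery, 3 fell over all genes tested (CYP1B1, AHRR and TIPARP), and 6 fell adjusted over the list alone (the same with CYP1A1, SERPINB2 and NFE2L2). Changes were negative in 10 of 11. The list passed by camera with adjusted p = 8.8e-21, and with adjusted p = 1.4e-04 with an estimated correlation and 1.5e-05 by fry. CYP1A1 had a log2 change of -1.92 (SE 0.59, adjusted p = 0.91), its DMSO arrays lay between 6.16 and 7.68, and its DMSO mean lay at percentile 1.23 of all genes. SERPINB2 had -1.57 (SE 0.54, adjusted p = 1.0). With the replicate block both passed, CYP1A1 with adjusted p = 0.047 and SERPINB2 with adjusted p = 0.0048. NFE2L2, the gene of the antioxidant regulator NRF2, was at -0.38 (SE 0.14, adjusted p = 1.0 over all genes). The changes of NQO1, CYP1A2 and ABCG2 were -0.35, -0.35 and -0.25, and those of ALDH3A1 and SLC7A5 were 0.06 and -0.0057, none of which passed. The gene of the receptor itself, AHR, had a log2 change of 0.31 (SE 0.11, adjusted p = 1.0).

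Among the 33 measured members of the list of other reported AHR-responsive genes, 2 fell over all genes tested, and 5 fell and 1 rose adjusted over the list alone. Besides EREG and STC2 the falls were VEGFA at -0.57, GREM1 at -0.71 (SE 0.14, adjusted p = 0.069 over all genes, 0.0058 with the replicate block) and THBS1 at -1.07 (SE 0.22, adjusted p = 0.095 over all genes). The rise was ID1 at 0.37 (SE 0.11, adjusted p = 0.85 over all genes), named after its values were seen. As a whole this list had camera adjusted p = 0.074, with 0.31 with an estimated correlation, and 0.017 downwards with the replicate block. The TGF-beta and YAP targets were shifted upwards, with 16 of 20 changes positive and adjusted p = 0.0098, but with adjusted p = 0.21 with an estimated correlation. Its members CTGF, ACTA2 and ID3 had log2 changes of 0.53, 0.43 and 0.35, and no member passed. The call of this list was lost without DMSO replicate 1 (adjusted p = 0.056) and without SR1 replicate 4 (adjusted p = 0.11). In other lists a few members passed over the list alone. INSIG1, an endoplasmic reticulum sterol regulator, was at -1.04 (SE 0.20, adjusted p = 0.053 over all genes, 0.0016 with the replicate block). In the hypoxia and glycolysis list these were HK2 at -0.59 and VEGFA. IER3 of the immediate early genes was at -0.74, with adjusted p = 0.0064 with the replicate block. DKK1 of the WNT pathway list was at 0.81. In the retinoid list ALDH1A3 fell while CRABP2 was at 0.58 (adjusted p = 0.39), and KDR of the endothelial markers was at -0.54 (adjusted p = 0.61, and 0.037 with the replicate block).

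No other list passed as a whole for SR1 against DMSO. Camera adjusted p was 0.074 for endoplasmic reticulum stress, migration and mesenchymal genes, extracellular proteases and inhibitors, cholesterol synthesis and uptake, and hypoxia and glycolysis. It was 0.11 for the integrated stress response, 0.13 for mitosis and 0.34 for inflammatory cytokines and NF-kB. With the replicate block, adjusted p was 0.017 upwards for migration and 0.013 upwards for mitosis. Downwards it was 0.017 for endoplasmic reticulum stress, the integrated stress response and inflammatory cytokines, 0.013 for proteases and 0.019 for cholesterol synthesis. None of these passed with an estimated correlation (without the block), where adjusted p was 0.21 for migration, 0.26 for endoplasmic reticulum stress and for proteases, 0.40 for cholesterol synthesis, and 0.74 for mitosis, the integrated stress response and inflammatory cytokines. Adjusted p was 0.75 for AHR complex and cofactors, 0.74 for tryptophan catabolism and transport, 0.16 for the NRF2 antioxidant response, 0.44 for collagens and matrix, 0.75 for interferon-stimulated genes, 0.53 for fatty acid synthesis (tested upwards, with a median of -0.016 and a mean of 0.031), 0.29 for DNA replication, 0.34 for p53 targets, 0.28 for immediate early genes, 0.91 for heat shock (tested downwards, though the median was 0.020 and the mean 0.024), 0.27 for the WNT pathway and 0.57 for retinoid and nuclear receptor genes (tested downwards, with a median of 0.0012 and a mean of -0.048). For glioma and astrocyte identity it was 0.30. For markers of other cell types it was 0.75 for haematopoietic, 0.65 for epithelial, 0.24 for neuronal and 0.75 for endothelial genes.

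The count for SR1 against DMSO was 45 with the replicate block, 5 higher and 40 lower, 25 with the title series as a block, 4 within SLI and 1 within SMI. It was 13 without DMSO replicate 1, 9 without DMSO replicate 2, 15 without SR1 replicate 1 and 13 without SR1 replicate 3, while CYP1B1 changed by -2.40 within SLI and -2.74 within SMI and passed with any 1 array left out. TIPARP did not pass without DMSO replicate 1, 2 or 4 or SR1 replicate 1 or 3, with adjusted p between 0.065 and 0.086, and SLC16A6 did not without DMSO replicate 2 (adjusted p = 0.062).

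**Figure D1:**
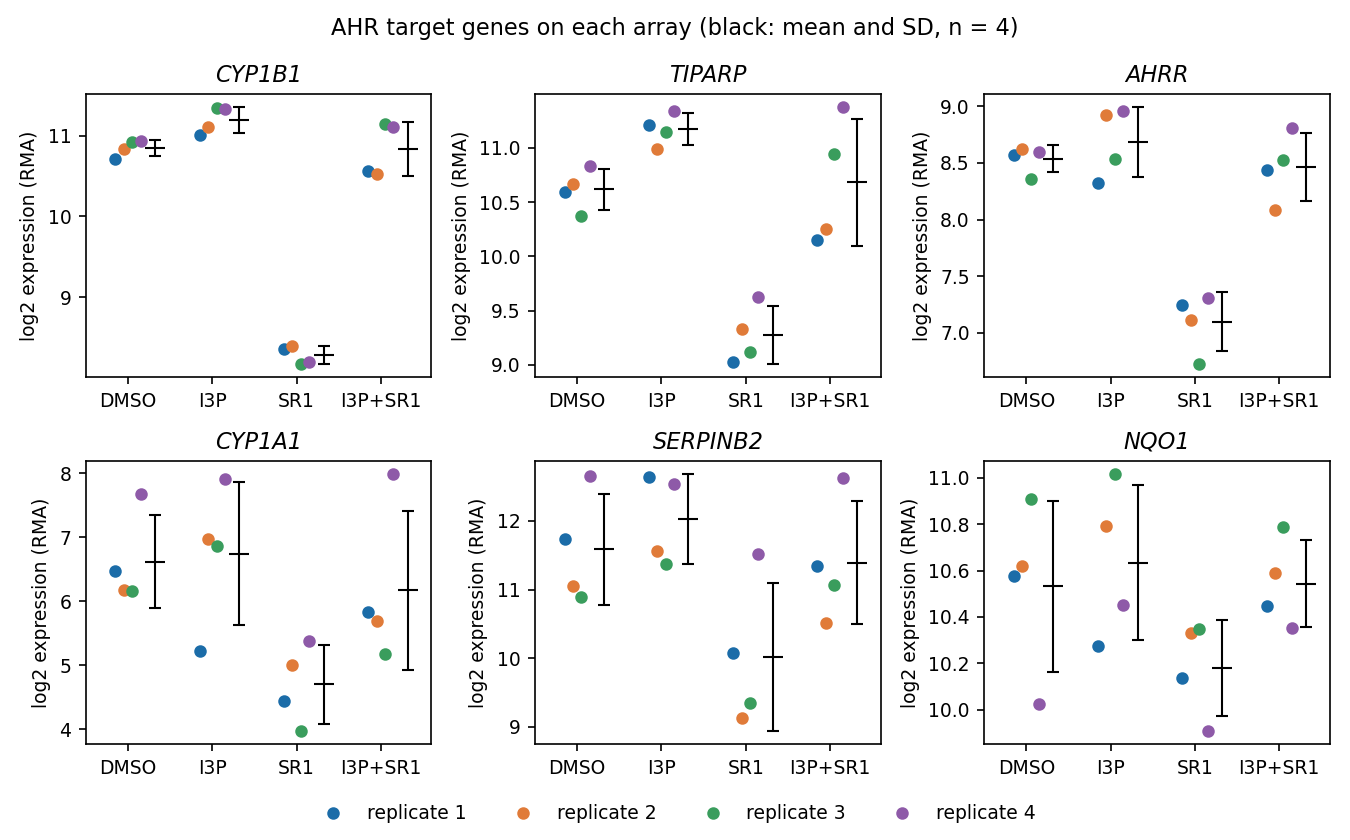
Log2 expression (vertical axes) of 6 AHR target genes on each of the 16 arrays, by treatment group (horizontal axes); points are single arrays coloured by replicate number, and black marks give the mean and SD (n = 4). CYP1B1, TIPARP and AHRR are lowest on the SR1 arrays, with CYP1B1 between 8.17 and 8.40 there and at 10.53 or above on every other array. For CYP1A1, SERPINB2 and NQO1 the SR1 arrays overlap with arrays of other groups.

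When I3P was added to SR1, all 22 genes lower with SR1 alone had positive changes over SR1, and 16 of them passed. The others of the 22 passed with the replicate block. CYP1B1 was at 10.84 ± 0.34 (SD, n = 4) in I3P+SR1, a rise of 2.56 (SE 0.15) over SR1 alone, or 5.89-fold, with adjusted p = 9.1e-08. SLC16A6 rose by 2.80 (SE 0.42, adjusted p = 0.0079), TIPARP by 1.41 (SE 0.22, adjusted p = 0.013) and AHRR by 1.37 (SE 0.18, adjusted p = 0.0022). In I3P+SR1 against SR1, 16 genes rose and 0 fell by limma, with 519 genes at an unadjusted p under 0.05, and for each of the 16 all 4 I3P+SR1 arrays lay above the SR1 mean. This comparison shows the response to I3P in the presence of the antagonist.

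The other named rises were STC2 by 1.41 (SE 0.19, adjusted p = 0.0031), PLEKHG4B by 1.52 (SE 0.19, adjusted p = 0.0022), EREG by 1.07 (SE 0.13, adjusted p = 0.0019) and ZIC2 by 1.21 (SE 0.16, adjusted p = 0.0030). ZNF295-AS1, RIPK4, PITPNC1 and the homeobox gene DLX2 passed with log2 changes of 1.29, 1.12, 0.92 and 0.89. DLX2 did not pass without SR1 replicate 1 (adjusted p = 0.072), SR1 replicate 2 (0.067), SR1 replicate 3 (0.066), I3P+SR1 replicate 3 (0.091) or I3P+SR1 replicate 4 (0.079). All 16 were among the 22 genes lower in SR1 against DMSO, where independent lists would share 0.025. Both comparisons use the SR1 arrays and share their chance values. Over all genes the changes correlated at r = -0.69 across genes, which are not independent replicates, and unchanged groups simulated with the same shared arrays gave -0.50 (range -0.52 to -0.46). The covariance was -0.0224. Simulated with the residual spread of the fit without a block, which holds the replicate differences, it was -0.0223 (range -0.0241 to -0.0198). With that of the replicate block it was -0.0148 (range -0.0159 to -0.0139). Differences that all groups of a replicate number share cancel between group means, so the spread without a block overstates this covariance. The observed value lies outside the range with the block. The simulated genes were independent of each other, which real genes are not, so that range does not decide the matter. When genes were called from a pair of SR1 arrays and tested against the other pair, each called gene had the opposite change in each of the 6 splits, with between 1 and 11 genes called.

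In the AHR target battery 3 of 11 members rose over all genes tested and 7 rose adjusted over the list alone (CYP1B1, AHRR, TIPARP, CYP1A1, CYP1A2, SERPINB2 and NFE2L2). The list passed with adjusted p = 8.6e-17, with 4.0e-04 with an estimated correlation and with 1.8e-05 by fry. CYP1A1 had a log2 change of 1.47 (SE 0.59, adjusted p = 1.0), SERPINB2 1.37 (SE 0.54, adjusted p = 1.0, and 0.015 with the replicate block) and CYP1A2 0.54 (SE 0.19, adjusted p = 1.0). NQO1, NFE2L2, ABCG2 and SLC7A5 were at 0.36, 0.35, 0.23 and 0.05, and ALDH3A1 was at -0.34. AHR itself was at -0.30 (SE 0.11, adjusted p = 1.0).

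Several other lists passed by camera in I3P+SR1 against SR1 but not with an estimated correlation. Other reported AHR-responsive genes were shifted upwards with adjusted p = 0.013, with 2 members passing over all genes and 6 higher and 1 lower adjusted over the list alone, and adjusted p = 0.16 with an estimated correlation. Besides EREG and STC2 the members higher were GREM1 at 0.70 (adjusted p = 0.0071 with the replicate block), VEGFA at 0.64, THBS1 at 0.85 and IL1B at 1.88 (SE 0.64), and the lower one was ID1 at -0.37, the last 3 named after their values were seen. Hypoxia and glycolysis genes had adjusted p = 0.011 upwards, with 4 members higher over the list alone (HK2 0.64, VEGFA 0.64, NDRG1 0.46 and SLC2A1 0.32) and adjusted p = 0.16 with an estimated correlation. Mitosis genes had adjusted p = 0.011 downwards, with 25 of 26 changes negative (TTK -0.33, CCNA2 -0.23), no member passing, and adjusted p = 0.73 with an estimated correlation. TGF-beta and YAP targets had adjusted p = 0.015 downwards, with CTGF at -0.66 and ID3 at -0.32, and adjusted p = 0.22 with an estimated correlation. Migration and mesenchymal genes had adjusted p = 0.037 downwards, with 21 of 28 changes negative (SNAI1 -0.42, PODXL -0.39), and adjusted p = 0.16 with an estimated correlation. With the replicate block the integrated stress response (adjusted p = 0.0055), endoplasmic reticulum stress (adjusted p = 0.016) and inflammatory cytokines (adjusted p = 0.0073) also passed upwards, against 0.76, 0.23 and 0.76 with an estimated correlation and no block. The call of other AHR-responsive genes was lost without I3P+SR1 replicate 1 (adjusted p = 0.074), SR1 replicate 2 (0.11) or I3P+SR1 replicate 4 (0.15), and that of hypoxia genes without SR1 replicate 3 (0.15) or I3P+SR1 replicate 4 (0.14). For mitosis these arrays were I3P+SR1 replicate 2 (0.057), SR1 replicate 3 (0.72) and I3P+SR1 replicate 4 (0.58), and for TGF-beta and YAP targets I3P+SR1 replicate 1 (0.074), I3P+SR1 replicate 3 (0.056) and SR1 replicate 4 (0.20). For migration genes they were SR1 replicate 1 (0.075), I3P+SR1 replicate 2 (0.056), I3P+SR1 replicate 3 (0.056), SR1 replicate 4 (0.15) and I3P+SR1 replicate 4 (0.17).

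Passing over their own lists alone, INSIG1 was at 0.98 (adjusted p = 0.091, and 0.0033 with the replicate block), ALDH1A3 at 0.96 (adjusted p = 0.072, and 0.0033 with the block) and IER3 at 0.76 (adjusted p = 0.10, and 0.0065 with the block). DKK1 was at -0.98 (adjusted p = 0.081, and 0.023 with the block), KDR at 0.56 (adjusted p = 0.47, and 0.032 with the block) and CRABP2 at -0.57 (adjusted p = 0.45). The count of 16 became 45 with the replicate block, 40 higher and 5 lower, 27 with the title series as a block, and 1 within SLI and 1 within SMI. It was 10 without SR1 replicate 2 and 10 without I3P+SR1 replicate 3, while CYP1B1 changed by 2.17 within SLI and 2.95 within SMI and passed with any 1 array left out. TIPARP did not pass without SR1 replicate 1, 2 or 3 or I3P+SR1 replicate 3, with adjusted p between 0.050 and 0.084.

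With both compounds present, the AHR targets lay near their level in DMSO. CYP1B1 differed by -0.01 (95% interval -0.32 to 0.30) between I3P+SR1 and DMSO, AHRR by -0.07 (-0.45 to 0.30) and TIPARP by 0.06 (-0.41 to 0.54). This comparison asks what difference from control remains under both compounds. By limma 0 genes passed, and 194 had an unadjusted p under 0.05. Over the 23 genes called for SR1 against DMSO, the change lay between -0.19 and 0.14 with a median of -0.01. The other battery members were at -0.45 (95% interval -1.71 to 0.81) for CYP1A1, -0.28 for ALDH3A1, -0.20 for SERPINB2, 0.19 for CYP1A2, 0.05 for SLC7A5, -0.027 for NFE2L2, -0.015 for ABCG2 and 0.01 for NQO1. The list had adjusted p = 0.88. Between the title series the direction differed, with CYP1B1 at -0.23 within SLI and 0.21 within SMI, AHRR at -0.33 and 0.19, and TIPARP at -0.43 and 0.56.

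The genes with the smallest p in I3P+SR1 against DMSO, none of which passed, were PLA2G2D at 0.63, IRF7 at 0.40, NEU3 at -0.53, UROC1 at -0.53 and CCR2 at 0.54, each with adjusted p = 1.0. IRF7, an interferon regulatory factor, passed over the list of interferon-stimulated genes alone. The epithelial markers were shifted upwards with adjusted p = 0.017, with 7 of 8 changes positive, no member passing (GRHL2 0.37, ESRP2 0.26, EPCAM 0.24), and adjusted p = 0.22 with an estimated correlation. That call was lost without DMSO replicate 1 (adjusted p = 0.36), DMSO replicate 2 (0.059), DMSO replicate 3 (0.11), I3P+SR1 replicate 1 (0.10) or I3P+SR1 replicate 2 (0.23). Several of these genes were dim. The DMSO means of CCR2, GRHL2 and ESRP2 lay at percentiles 4.06, 2.99 and 2.27 of all genes, and the I3P+SR1 mean of UROC1 at 0.905. With the replicate block mitosis genes also passed, downwards, with adjusted p = 0.028, against 0.995 with an estimated correlation and no block.

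**Figure D2:**
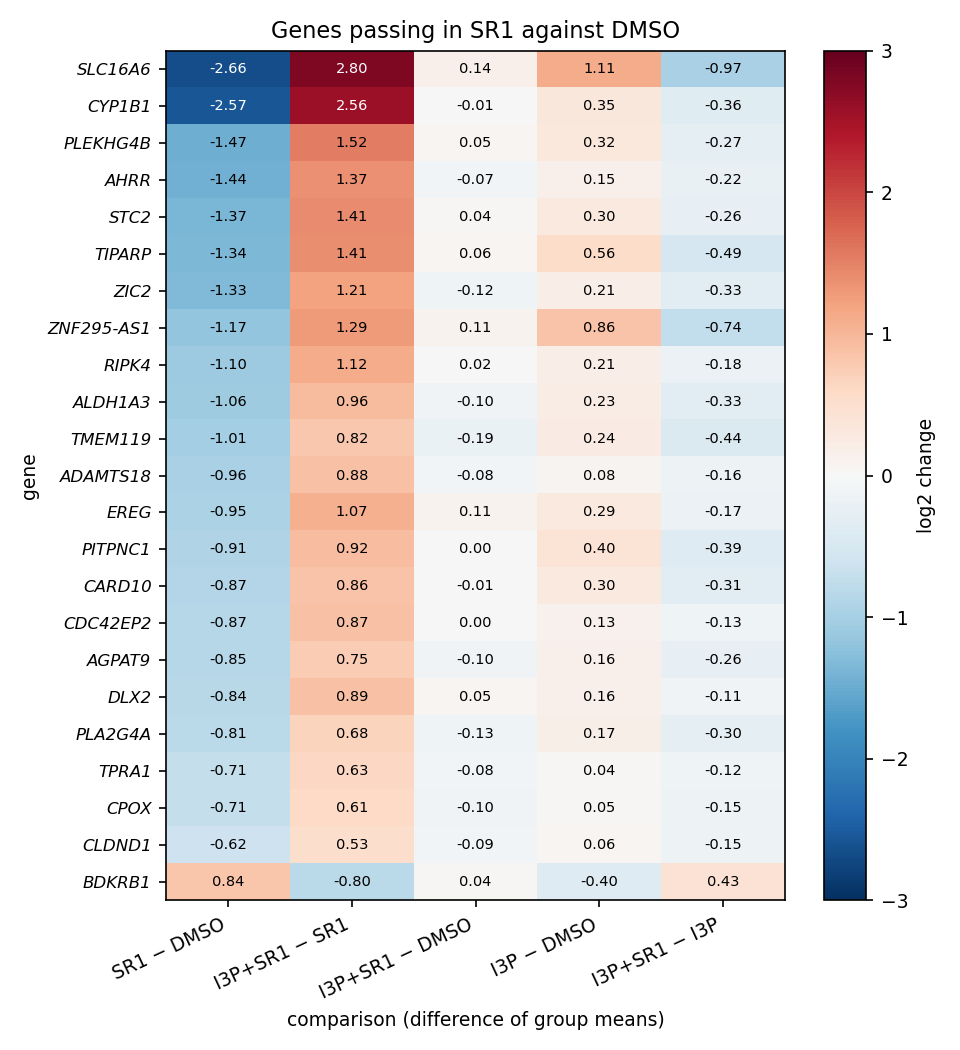
Log2 change (colour scale and printed value) of the 23 genes that passed for SR1 against DMSO (rows) in 5 differences of group means (columns). The 22 genes lower with SR1 have positive values in I3P+SR1 minus SR1, and all 23 lie between -0.19 and 0.14 in I3P+SR1 minus DMSO.

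I3P alone changed no gene past the threshold. TIPARP was higher than in DMSO by 0.56 (SE 0.22, 95% interval 0.08 to 1.03, adjusted p = 0.999) and CYP1B1 by 0.35 (SE 0.15, 95% interval 0.04 to 0.65, adjusted p = 0.999). Within SLI and SMI the values were 0.47 and 0.64 for TIPARP and 0.28 and 0.41 for CYP1B1. By replicate number, the CYP1B1 differences were 0.30, 0.26, 0.42 and 0.40. The SE and intervals come from the fit without a block, which leaves differences between replicate numbers in the spread. I3P against DMSO is the comparison named in the title of the series. By limma 0 genes passed, and 395 had an unadjusted p under 0.05. With the replicate block the limma count was also 0, with 882 genes at an unadjusted p under 0.05. The genes with the smallest p, which did not pass, were ZNF295-AS1 at 0.86, the potassium channel gene KCNK12 at -0.94, PRDM1 at 0.86, NEU3 at -0.65 and LGR5 at 0.75, each with adjusted p = 0.999. The DMSO means of ZNF295-AS1 and LGR5 lay at percentiles 2.15 and 1.62 of all genes, and the I3P mean of KCNK12 at 0.199.

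Of the 11 battery members 8 had positive changes, and the list had adjusted p = 0.13, which did not pass, and 0.034 upwards with the replicate block, which did. With the block, other reported AHR-responsive genes (adjusted p = 0.0019) and inflammatory cytokines (0.0024) also passed upwards and mitosis genes (1.7e-05) downwards. With an estimated correlation and no block, none of these passed, with adjusted p of 0.60 for the battery (0.74 by fry) and for the other AHR-responsive genes, 0.85 for cytokines and 0.84 for mitosis, whose genes had an estimated correlation of 0.617. Neither test was run with the block, so these values do not decide the blocked calls. SERPINB2 was at 0.44 (SE 0.54), NFE2L2 at 0.23, AHRR at 0.15, CYP1A1 at 0.12 (95% interval -1.14 to 1.38, with -0.23 within SLI and 0.47 within SMI), NQO1 at 0.10 and ABCG2 at 0.05, while SLC7A5 was at -0.01, CYP1A2 at -0.17 and ALDH3A1 at -0.18. The retinoid and nuclear receptor genes were shifted upwards with adjusted p = 0.013, with 13 of 15 changes positive, no member passing (DHRS3 0.43, PPARG 0.33, CYP26B1 0.30), and adjusted p = 0.60 with an estimated correlation. It was lost without I3P replicate 2 (adjusted p = 0.15), I3P replicate 3 (0.072), DMSO replicate 3 (0.24) or DMSO replicate 4 (0.059). The DMSO mean of PPARG lay at percentile 2.54 of all genes. LGR5 and IRF7 (0.37) passed over the WNT list alone and the interferon list alone. Without I3P replicate 1, the array that stood apart, the count by limma was also 0, with 271 at an unadjusted p under 0.05.

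With SR1 added to I3P, AHR targets had negative changes that did not pass. CYP1B1 was at -0.36 (SE 0.15, 95% interval -0.67 to -0.05, adjusted p = 0.999) in I3P+SR1 against I3P, TIPARP at -0.49 (SE 0.22, 95% interval -0.96 to -0.02, adjusted p = 0.999) and AHRR at -0.22. Within SLI and SMI the values were -0.51 and -0.20 for CYP1B1 and -0.90 and -0.085 for TIPARP. By limma 0 genes passed, and 466 had an unadjusted p under 0.05. With the replicate block the limma count was also 0, with 972 genes at an unadjusted p under 0.05. The comparison asks how the antagonist changes expression when I3P is present. The smallest p values, not passing, belonged to PLA2G2D (0.62), MAG (-0.84), TBKBP1 (-0.60), NKAIN1 (0.67) and UBE2B (-0.50), each with adjusted p = 0.999. The I3P+SR1 mean of MAG lay at percentile 0.527 of all genes.

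In the battery 9 of 11 changes were negative, with adjusted p = 0.077, and with 0.021 downwards with the replicate block. With the block, proteases (adjusted p = 0.032) and inflammatory cytokines (0.029) also passed downwards and mitosis genes (0.039) upwards. With an estimated correlation and no block, none of these passed, with adjusted p of 0.64 for the battery (0.71 by fry), 0.69 for proteases, and 0.88 for cytokines and for mitosis. These tests were not run with the block and so do not decide the blocked calls. SERPINB2 was at -0.64, CYP1A1 at -0.57, NFE2L2 at -0.25, ALDH3A1 at -0.10, NQO1 at -0.09 and ABCG2 at -0.07, and CYP1A2 and SLC7A5 were at 0.37 and 0.06. With 1 array left out, the change ranged from -1.05 to -0.35 for SERPINB2, -1.18 to -0.18 for CYP1A1 and -0.35 to -0.12 for NFE2L2. The retinoid and nuclear receptor genes were shifted downwards with adjusted p = 0.031, with CYP26B1 at -0.54, DHRS3 at -0.41, ALDH1A3 at -0.33 and RARB at -0.32, and adjusted p = 0.64 with an estimated correlation. It was lost without I3P replicate 2 (adjusted p = 0.15), I3P replicate 3 (0.078), I3P+SR1 replicate 3 (0.14) or I3P+SR1 replicate 4 (0.071). CYP26B1, a retinoic acid hydroxylase, passed over this list alone. The AHR target battery passed without I3P replicate 1 (adjusted p = 0.046) and without I3P+SR1 replicate 4 (adjusted p = 0.0017).

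The response of CYP1B1 to I3P differed with and without SR1. As the arrays are labelled, it was higher by 2.56 in I3P+SR1 than in SR1, against a difference of 0.35 between I3P and DMSO, and the interaction was 2.21 (SE 0.21, 95% interval 1.77 to 2.65, adjusted p = 1.4e-04). It was the only gene of 14040 to pass for the interaction by limma, with 283 at an unadjusted p under 0.05. The difference between I3P+SR1 and SR1 was larger than that between I3P and DMSO in each of the 4 replicates, with values of 2.21, 2.13, 2.98 and 2.91 against 0.30, 0.26, 0.42 and 0.40.

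As a group the AHR target battery had positive interactions in 10 of 11 members, with adjusted p = 8.6e-10, with 0.0050 with an estimated correlation and 0.0044 by fry. Members higher over the list alone numbered 2, CYP1B1 and AHRR (1.22, SE 0.25, adjusted p = 1.0 over all genes). CYP1A1 was at 1.35, SERPINB2 at 0.93, TIPARP at 0.85, CYP1A2 at 0.71, NQO1 at 0.26, ABCG2 at 0.18, NFE2L2 at 0.13, SLC7A5 at 0.07 and ALDH3A1 at -0.16. With 1 array left out, the interaction ranged from 0.75 to 1.74 for CYP1A1 and from 0.52 to 1.43 for SERPINB2. PLEKHG4B, STC2, ZIC2 and EREG were at 1.20, 1.11, 1.00 and 0.78, each with adjusted p = 1.0 over all genes, and EREG and STC2 passed over the list of other reported AHR-responsive genes alone. For CYP1B1 the interaction was 1.89 within SLI and 2.54 within SMI, and 0 genes passed by limma within SLI alone, with 398 at an unadjusted p under 0.05.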

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

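The counts over other splits of the arrays were chosen before their results were seen, and the exchange of groups within replicate numbers and the tests on pairs of SR1 arrays, on exchanged labels, on I3P replicate 1, on shared arrays by simulation and on a smaller response to I3P were chosen after.

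CYP1B1 drew attention because its response to I3P differed between cells with and without SR1, by 2.21 on the log2 scale in the interaction. Of 100 assignments of the 16 arrays, the real one included, 2 gave as many genes as the real 1 for the interaction, and the highest other assignment gave 2. With the groups exchanged only within replicate numbers it was also 2 of 100 splits, with 1 as the highest other. Both kinds of assignment exchange all 4 groups and so also remove the effect of SR1 alone. They therefore cannot exclude chance for the interaction itself.

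For SR1 against DMSO (23 genes) and I3P+SR1 against SR1 (16 genes), 1 of 35 splits of the 8 arrays, the real one, gave as many genes, and the highest other gave 0. The replicate numbers pair these arrays, and the 8 splits that part all pairs, with 0 as the highest other, are too few for a share under 0.05. The remaining splits put same-numbered arrays into the same group.

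Within groups, single arrays lay far from the rest for several named genes, as measured by the gap to the nearest array over the range of the group. This ratio was 0.866 for AHR and 0.932 for BDKRB1 on DMSO replicate 2, 0.889 for TTK on DMSO replicate 3, and 0.862 for ESRP2 and 0.940 for MAG on DMSO replicate 4. It was 0.890 for NKAIN1 on I3P replicate 1. On the SR1 arrays it was 0.836 for KDR on replicate 2, 0.839 for ID3 and 0.858 for INSIG1 on replicate 3, and 0.856 for PLEKHG4B on replicate 4. On the I3P+SR1 arrays it was 0.869 for MAG on replicate 1 and 0.850 for IER3 on replicate 4. These were 12 of 252 groups tested, where chance gives about 12.6.

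Unnamed features of the array, left out of the comparisons, also changed in a limma fit of all features. Feature 16813856 changed by -1.25 (SE 0.20) in SR1 against DMSO and by 1.20 (SE 0.20) in I3P+SR1 against SR1, feature 16787536 by -1.10 (SE 0.21) and 1.15 (SE 0.21), and feature 16795820 by -0.92 (SE 0.15) in SR1 against DMSO.

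With SR1 alone 22 genes were lower than in DMSO, while the I3P+SR1 arrays lay near the DMSO level. Chance shared through the SR1 arrays is argued against for the called genes. Those called from a pair of SR1 arrays had a median opposite change of at least 0.901 against the other pair in each of the 6 splits. Between 1 and 11 genes were called. Over all genes, the changes from separate pairs correlated between -0.22 and 0.059. Differences between replicate numbers enter both of these changes with the same sign, which pushes the correlations upwards. They therefore cannot decide whether the changes of all genes were opposite. An exchange of the SR1 and I3P+SR1 labels in a single title series is also argued against, since the SR1 array was the lowest for CYP1B1 in 4 of 4 replicates. An exchange of these labels in all replicates cannot be told apart from the order as labelled, since over the 14017 genes not called the changes in I3P against DMSO and in I3P+SR1 against SR1 correlated at 0.226, against the negative value an exchange would give, but with an exact two-sided permutation p of 0.086, and at 0.102 without I3P replicate 1. All 16 genes called in I3P+SR1 against SR1 were also higher with I3P alone (exact permutation p = 0.029, or 0.125 within replicate numbers). This goes against an exchange only if I3P acts the same way with and without SR1. Over all genes the changes in these comparisons correlated at 0.237, against -0.043 to 0.035 simulated. The simulated genes were independent, which real genes are not, so that range cannot decide the matter. Over the genes not called, another split of the I3P and DMSO arrays reached 0.240. As labelled, the interaction showed that SR1 acted less on CYP1B1 with I3P (2.21, adjusted p = 1.4e-04), and this biological reading stays open because it rests on the labels.

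No gene passed for I3P against DMSO, and the limma counts of 0 stand beside 395, 466 and 194 genes at an unadjusted p under 0.05 in I3P against DMSO, I3P+SR1 against I3P and I3P+SR1 against DMSO. In this fit without a block, each of these counts is below a share of 0.05 of the 14040 genes, which unchanged genes would give on average. So is the 412 of SR1 against DMSO, where 23 genes passed, so a count below that share does not show a lack of response. With the replicate block the counts were 882, 972 and 370, and those of I3P against DMSO and I3P+SR1 against I3P lay above that share. Every one of the 35 splits reaches a count of 0 by construction, so the splits decide nothing here, and the highest other counts were 1, 1 and 0. Whether the spread of I3P replicate 1 hid a response was not decided. Without that array 0 genes passed by limma, with 271 at an unadjusted p under 0.05, or 776 with the replicate block. Fewer I3P arrays enter those fits, so a small response could still be missed. A response smaller than that seen with SR1 stays open, since the genes called in I3P+SR1 against SR1 were higher with I3P on average (exact permutation p = 0.029), but exchanges within replicate numbers alone gave 0.125, the smallest they can give.

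I3P replicate 1 stood apart, with correlations over genes of 0.910 at most with the other arrays. The value lies below 0.921, the lowest correlation among the other 15. An exchange of its label with another of the 16 arrays would leave all these correlations unchanged. Such an exchange would not account for the low correlations, and they cannot tell whether it took place. A trend on brightness left by the normalization is argued against as the whole cause, since the SD of its deviations from the other I3P arrays was 0.516 before and 0.510 after such a trend was removed, and the highest among the other arrays was 0.413. RNA quality was not measured in the values used here and stays open, and no biological explanation was tested.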

How the results depend on the processing

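The array weights, the replicate block with array weights and the replicate block without I3P replicate 1 were chosen after seeing the data.

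The counts for I3P against DMSO and for I3P+SR1 against DMSO were 0 by limma in every setting run, with 255 to 882 and 92 to 785 genes at an unadjusted p under 0.05. The count for I3P+SR1 against I3P was 0 (269 to 1057 unadjusted) except for 1 gene within SLI, and that for the interaction was 1 except for 0 within SLI (398 unadjusted). The count for SR1 against DMSO (23) was 45 with the replicate block, 4 within SLI, 1 within SMI, 6 with only the groups compared, 39 with array weights, 143 with the replicate block and array weights, and 80 with the replicate block without I3P replicate 1. With 1 array left out it ranged from 9 to 25. The count for I3P+SR1 against SR1 (16) was 45 with the replicate block, 32 with the replicate number as a random block, 27 with the title series as a block, 1 within SLI, 1 within SMI, 7 with only the groups compared, 126 with the replicate block and array weights, and 104 with the replicate block without I3P replicate 1. With 1 array left out it ranged from 10 to 18. Fewer arrays enter the fits within a series and on only the groups compared, and the cause of the other differences was not tested. Quantile normalization and centring moved the median of all genes by at most 0.0097.

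Same-number correlations were -0.066 to 0.51 for I3P against DMSO and -0.088 to 0.55 for I3P+SR1 against I3P, with the negative values in replicate 1, and 15 of 16 arrays correlated best with their own number (the exception was I3P replicate 1). There the replicate block moved no count of genes and gave the battery camera adjusted p = 0.034 and 0.021. With an estimated correlation and no block the values were 0.60 and 0.64, and the estimated correlation was not run with the block. Apart from these and the values given with the comparisons, the block changed no call of a list. With 1 array left out the battery's adjusted p ranged from 0.0017 to 0.465 for I3P+SR1 against I3P, and from 0.117 to 0.939 for I3P+SR1 against DMSO, where its direction turned without I3P+SR1 replicate 1 or 2 or DMSO replicate 4.

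Of the named genes that turned direction in any setting, 0 had passed, and the cause was not tested. Within SLI, I3P against DMSO gave CYP1A1 -0.23, ABCG2 -0.13, CYP1A2 0.13 and NQO1 -0.0656, the interaction gave NFE2L2 -0.0805, SR1 against DMSO gave ALDH3A1 -0.11, and I3P+SR1 against DMSO gave NQO1 -0.0809 and TIPARP -0.43. Within SMI, SLC7A5 was at 0.11 in I3P against DMSO, -0.0204 in I3P+SR1 against I3P, -0.0667 in the interaction and 0.0463 in SR1 against DMSO, and ALDH3A1 at 0.23 in I3P+SR1 against I3P. For I3P+SR1 against DMSO, SMI gave CYP1B1 0.21, AHRR 0.19, ABCG2 0.13, ALDH3A1 0.11, NFE2L2 0.0339, SERPINB2 0.0712 and ESRP2 -0.0186. With array weights SLC7A5 was at 0.0742 in I3P against DMSO and -0.0177 in I3P+SR1 against I3P, and NQO1 at -0.0550 in I3P+SR1 against DMSO. With the replicate block and array weights SLC7A5 was at 0.0411 in I3P against DMSO and NQO1 at -0.0178 in I3P+SR1 against DMSO. With the replicate block without I3P replicate 1 SLC7A5 was at 0.0632 in I3P against DMSO, -0.0151 in I3P+SR1 against I3P and -0.0094 in the interaction. After quantile normalization SLC7A5 was at 0.0212 in I3P against DMSO and CYP1B1 at 0.0027 in I3P+SR1 against DMSO.

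With 1 array left out, changes in I3P against DMSO ranged from -0.27 to 0.63 for CYP1A1, -0.0374 to 0.13 for ABCG2, -0.0685 to 0.23 for NQO1 and -0.11 to 0.0983 for SLC7A5. In I3P+SR1 against I3P they ranged from -0.14 to 0.0099 for ABCG2, -0.26 to 0.0427 for ALDH3A1, -0.21 to 0.0371 for NQO1 and -0.0706 to 0.15 for SLC7A5. In SR1 against DMSO they ranged from -0.0410 to 0.17 for ALDH3A1 and -0.12 to 0.12 for SLC7A5, in I3P+SR1 against SR1 from -0.0773 to 0.17 for SLC7A5, and in the interaction from -0.0649 to 0.18 for SLC7A5. In I3P+SR1 against DMSO they ranged from -0.12 to 0.0907 for CYP1B1, -0.19 to 0.0550 for AHRR, -0.17 to 0.24 for TIPARP, -0.10 to 0.0653 for ABCG2, -0.0761 to 0.0178 for NFE2L2, -0.16 to 0.14 for NQO1, -0.61 to 0.16 for SERPINB2 and -0.0830 to 0.16 for SLC7A5. Over 147 gene results and 4361 alternatives, 4076 kept direction and side of the threshold, 100 lost the call, 105 gained one and 80 turned direction. Signal over background was not assessed, which limits what dim genes can show.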

Other observations

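The tests in this part (the genes named with the replicate block and the shared direction of I3P) were all chosen after the values were seen.

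With the replicate number as a block, further genes passed, and the ones given here were picked after their values were seen. IL1B, which encodes interleukin 1 beta, changed by -1.70 (SE 0.16, adjusted p = 5.8e-04) in SR1 against DMSO and by 1.88 (SE 0.16, adjusted p = 2.4e-04) in I3P+SR1 against SR1, against adjusted p = 1.0 for both without the block. THBD, which encodes the anticoagulant receptor thrombomodulin, changed by -1.06 (SE 0.18) and 1.12 (SE 0.18), and the circadian transcription factor gene NPAS2 by -0.82 (SE 0.11) and 0.88 (SE 0.11). RGS4, a regulator of G protein signalling, changed the other way, by 0.74 (SE 0.13) and -0.73 (SE 0.13). IL1A rose by 0.80 (SE 0.15) and BCL3 by 0.62 (SE 0.12) in I3P+SR1 against SR1, and RSPO3 and NUAK2 rose by 0.65 (SE 0.12) and 0.79 (SE 0.14) in SR1 against DMSO. The block called 45 genes in each comparison, 34 of them in both, and all 34 went in opposite directions. These comparisons share the SR1 arrays, which by itself favours opposite directions, and no such count was simulated for unchanged groups. The 23 and 16 genes called without the block were all among them.

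A hypothesis is that I3P without SR1 raises the genes that respond to it in the presence of SR1, by less. The 16 genes called in I3P+SR1 against SR1 were tested in I3P against DMSO, which shares no array with that comparison. All 16 were higher with I3P, by 0.35 on average (0.08 to 1.11), against 1.30 on average in the presence of SR1. Their mean was 8.99 ± 0.15 (SD, n = 4) in DMSO and 9.34 ± 0.05 (SD, n = 4) in I3P, higher in 4 of 4 replicates by 0.14 to 0.49, with an exact two-sided permutation p of 0.029, the smallest that 70 directed splits can give. Those splits ignore the replicate numbers, and the 16 exchanges within numbers gave an exact permutation p of 0.125, the smallest they can give, so they cannot pass 0.05. Without I3P replicate 1 the mean change was 0.37 (exact permutation p = 0.029 from 35 splits). A small response of these 16 genes to I3P alone, which the test of single genes did not call, stays open. Of the 16, CYP1B1, AHRR and TIPARP belong to the AHR target battery, and that list as a whole did not pass for I3P against DMSO without the replicate block (camera adjusted p = 0.13). The order of the SR1 and I3P+SR1 labels is assumed here, and the hypothesis was found and tested on the same data.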
